A study of Homo sapiens with 12 samples.

How the data were processed

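Extracellular vesicles were collected from 6 cancer cell lines (HT55, Car-1, MDST8, SW1116, Hutu80 and RCM-1), with 2 libraries per line, 12 in all. Per the labels' protocols, the cells grew in DMEM/F12 medium with fetal bovine serum and antibiotics, vesicles were separated from the conditioned medium by ultrafiltration followed by size-exclusion chromatography, and RNA was extracted with a kit made for serum and plasma. Libraries were made with IsoSeek, a small RNA protocol for low input that adds a unique molecular identifier to each molecule, per the labels' protocols. The genome build was hg38, per the submitters' processing notes. The aligner, the miRNA annotation release, the counter and whether the identifiers were collapsed are not given in the sources used here. If identifiers were not collapsed, counts are not independent molecules, so the intervals given cover counting error only.

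The deposited count table holds whole-number counts of 1636 mature miRNAs in each library, not normalised. A second deposited table holds log2 values, which equal log2(CPM + 1) of the count table over all 19632 cells (largest difference 5e-14), where CPM is the count scaled to a common library total with no further scaling. The groups are the lines, read from the labels. The series describes 3 lines of one molecular subtype and 3 of another, but neither the labels nor the column names used here tie a line to a subtype, so no comparison of subtypes was made and none was inferred from the values.

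Of the 1636 miRNAs, 413 were at 0 in every library. The edgeR function filterByExpr with the line as group kept 318 miRNAs, which hold 99.7% of the 3141138 counts. Counts were scaled by trimmed-mean (TMM) factors, which ran from 0.641 to 1.46, and tested with edgeR's quasi-likelihood F-test (glmQLFit with robust estimation, glmQLFTest). All 12 libraries entered a single fit with 1 mean per line and no block, because a line has only 2 libraries. The common biological coefficient of variation was 0.304. The same fit gave the test across all 6 lines, each line against the mean of the other 5 on the log scale, and all 15 pairs of lines. Benjamini-Hochberg adjustment was applied per comparison, with a threshold of 0.05. The SE of a log2 difference was taken as its size divided by the square root of F. Levels printed for the other lines are arithmetic means of scaled CPM, so their ratio can differ from the fitted difference.

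There were 15 lists of miRNAs, written before the data were examined together with the tests, the alternatives and the rule for naming miRNAs. Lists with at least 3 tested members (12 of the 15) were tested per line with limma's camera on voom values, with a preset correlation of 0.01 and again with an estimated one, and adjusted over all 72 tests. The 10 ways to split the 6 lines into 3 and 3 were tested with edgeR on counts summed per line, and only their range and median are given. Detection was compared after thinning each library to the smallest total, over 100 draws per library. The text names, per line and direction, up to 5 miRNAs with the largest difference among those with an adjusted p below 0.05, a mean of at least 100 CPM (in the line if higher, in the other lines if lower) and both libraries outside the range of the other 10. It also names up to 6 tested members per list with the highest mean CPM, the 10 miRNAs with the largest mean share of counts and the 10 with the smallest adjusted p across lines. Any other miRNA named is said to have been chosen after its values were seen, and those in the closing section were all so chosen unless they meet this rule. For a miRNA with at most 3 counts on one side of a comparison, the ratio of unscaled CPM, pooled over libraries, is given with its 95% counting interval in place of the fitted difference. Where any single line had at most 3 counts, the text gives levels and the test in place of the fitted difference for a miRNA named by line, since a fitted value then leans on the prior count; the order of these miRNAs by fold has the same limit.

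Alternatives were RLE size factors, library totals as the only scaling, no filter on low counts, a filter of 10 CPM in 2 libraries, DESeq2, limma-voom, limma-trend on the deposited log2 values, the replicate number as a block, leaving out the 10 most abundant miRNAs, and leaving out each library in turn. When a library is left out, the remaining library of that line is assumed to vary like the other lines. The list tests were not run in DESeq2 or limma-voom. The filter of 10 CPM in 2 libraries is called the stricter filter below, but it was looser than the main filter. With it 7 miRNAs of the Xq27 list passed across lines, against 3 tested in the main fit. On data simulated for the contrast of Hutu80 with the other lines (293 miRNAs), the edgeR procedure recovered 3 of 15 changes of 2-fold, 18 of 20 of 4-fold and 17 of 20 of 8-fold, with 0 false calls among 238 unchanged miRNAs. In that test most changes of 2-fold were missed. The other lines were simulated alike, rises and falls in Hutu80 were made in equal number, and all miRNAs had the same spread. False calls from uneven scaling or uneven spread were therefore not tested.

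Hairpin positions and host genes came from GENCODE release 29 (GRCh38), matched by name, 1-based. Of the 318 tested miRNAs, 313 matched a hairpin and 275 a single one. Hairpins within 50000 bp of each other were grouped into 28 clusters, a distance chosen after the data were seen. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.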

Results

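Small RNA was sequenced from extracellular vesicles of 6 cancer cell lines, HT55, Car-1, MDST8, SW1116, Hutu80 and RCM-1, with 2 libraries per line and 12 libraries in all. Extracellular vesicles are membrane-bound particles that cells shed into the medium, and they carry microRNAs (miRNAs), short RNAs that lower the output of the messenger RNAs they pair with. The series describes its lines as 3 of consensus molecular subtype 2 and 3 of subtype 4. Since no label used here says which line belongs to which subtype, the lines were compared with each other and the subtypes were not compared. The count table held 1636 mature miRNAs, of which 1223 had a count in at least 1 library and 318 were tested. Total counts per library ran from 71831 in Hutu80 replicate 1 to 622800 in SW1116 replicate 1, a ratio of 8.67. HT55 had 138753 and 206808 counts, Car-1 172774 and 137766, MDST8 339853 and 306811, SW1116 622800 and 498342, Hutu80 71831 and 100531, and RCM-1 172320 and 372549. A single count was therefore worth between 1.61 CPM (counts scaled to a common library total) in the deepest library and 13.9 CPM in the shallowest. Levels below are CPM scaled by trimmed-mean factors, given as mean ± SD over the 2 libraries of a line unless called unscaled, and differences are on the log2 scale with their standard error (SE). The labels do not say whether the 2 libraries of a line came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

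Over the 318 tested miRNAs, Spearman correlations between the 2 libraries of a line ran from 0.933 to 0.958 (6 pairs), and those between libraries of different lines from 0.674 to 0.925 (60 pairs). These correlations are across miRNAs, which are not independent replicates. Pairs of RCM-1 and SW1116 libraries included the highest value between lines (0.890 to 0.925). Pairs of HT55 and Hutu80 libraries included the lowest (0.674 to 0.750). The 2 libraries of every line differed by more than sampling noise, with a chi-square per degree of freedom of 8.10 in Hutu80 to 51.2 in Car-1, so none was counted as a repeat deposit.

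**Figure D1:**
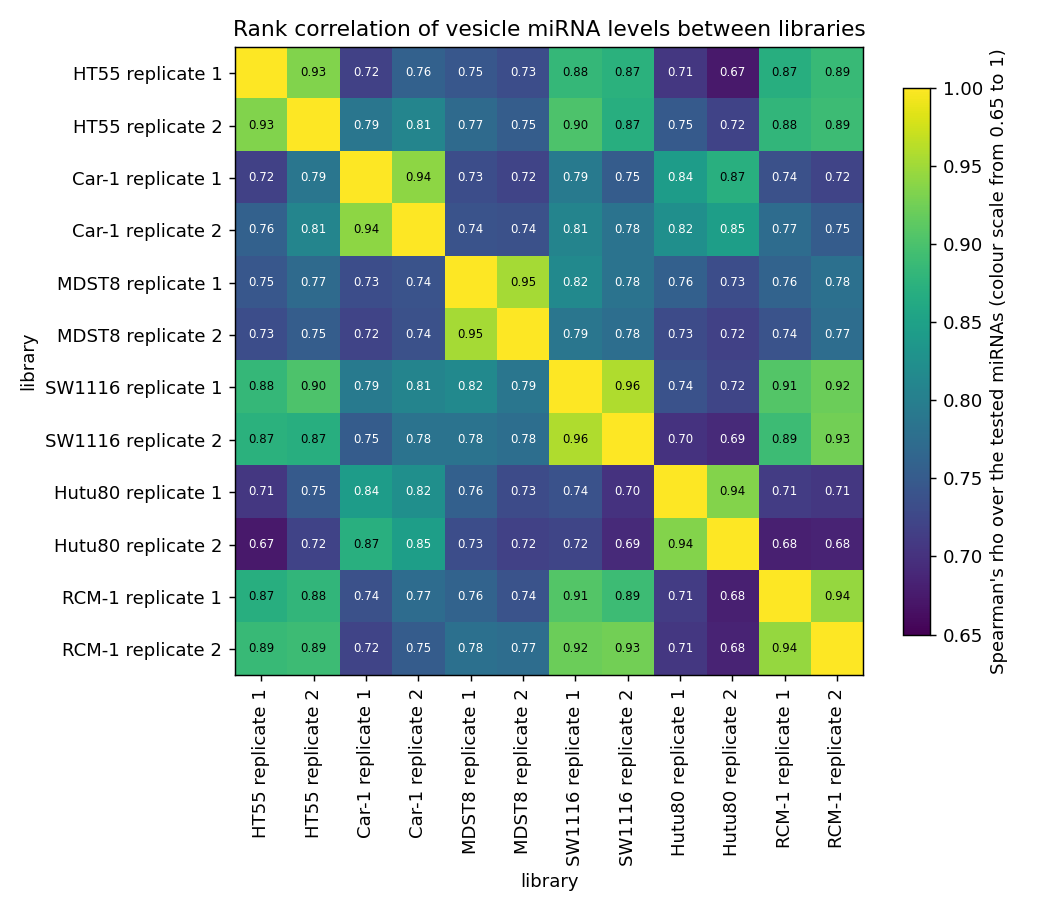
Spearman correlation between each pair of the 12 libraries over the 318 tested miRNAs, as a heat map with both axes listing the libraries and colour giving the correlation. The 6 pairs of replicates lie between 0.933 and 0.958, and pairs from different lines between 0.674 and 0.925.

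The miRNA with the largest mean share of counts was miR-10a-5p, which lies inside the HOXB gene cluster (chromosome 17, 48579838 to 48579947, in an intron of HOXB3). It made up 27.6% ± 1.68 (SD, n = 2) of counts in SW1116, 22.8% ± 0.22 in RCM-1 and 17.3% ± 1.11 in HT55, against 10.8% ± 0.94 in Hutu80, 9.21% ± 1.63 in Car-1 and 9.05% ± 0.75 in MDST8. Next came miR-21-5p, a miRNA raised in many tumours, at 17.7% ± 3.40 in MDST8 and 4.10% ± 1.02 in HT55. miR-30a-5p took 11.3% ± 1.02 of Hutu80 counts and 0.209% ± 0.050 of RCM-1 counts. The other miRNAs among the 10 with the highest mean share were miR-92a-3p (6.76% over all libraries), let-7a-5p (6.49%), let-7f-5p (5.37%), let-7b-5p (4.69%), miR-200c-3p (4.31%), miR-182-5p (3.12%) and miR-222-3p (2.67%). The 10 most abundant miRNAs of each library took 58.9% to 78.0% of its counts.

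The first comparison asked which vesicle miRNAs differed among the 6 lines. The miRNA with the smallest p-value was miR-30a-3p (adjusted p = 9.99e-14), at 704 ± 206 CPM in RCM-1 and 43411 ± 2368 in Hutu80. miR-146a-5p, which is induced by NF-kB signalling (chromosome 5, 160485352 to 160485450, in an exon of the non-coding gene MIR3142HG), ranged from 1193 ± 561 CPM in SW1116 to 28846 ± 641 in MDST8. miR-375-3p, a miRNA of gut epithelium and endocrine cells (chromosome 2, 219001645 to 219001708, intergenic), ranged from 220 ± 48.6 CPM in MDST8 to 7073 ± 1341 in RCM-1. miR-205-5p, a miRNA of squamous and basal epithelia, ranged from 41.1 ± 13.7 CPM in MDST8 to 4109 ± 1971 in Car-1. In edgeR's quasi-likelihood F-test, 217 of 318 miRNAs passed a Benjamini-Hochberg adjusted p of 0.05, and 230 had an unadjusted p below 0.05. After miR-30a-3p, the smallest adjusted p-values were those of miR-509-3p (4.9e-13), miR-146a-5p (1.19e-12), miR-205-5p (1.22e-12), miR-375-3p (1.71e-12), miR-100-5p and miR-192-5p (1.99e-12 each), miR-203a-3p (2.23e-12), miR-30c-2-3p (2.34e-12) and miR-194-5p (2.46e-12). miR-30c-2-3p, from the same chromosome 6 cluster as miR-30a-3p, was at 46.7 ± 12.9 CPM in SW1116 and 2869 ± 421 in Hutu80. The epidermal miRNA miR-203a-3p was at 221 ± 68.7 CPM in MDST8 and 5378 ± 334 in RCM-1.

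**Figure D2:**
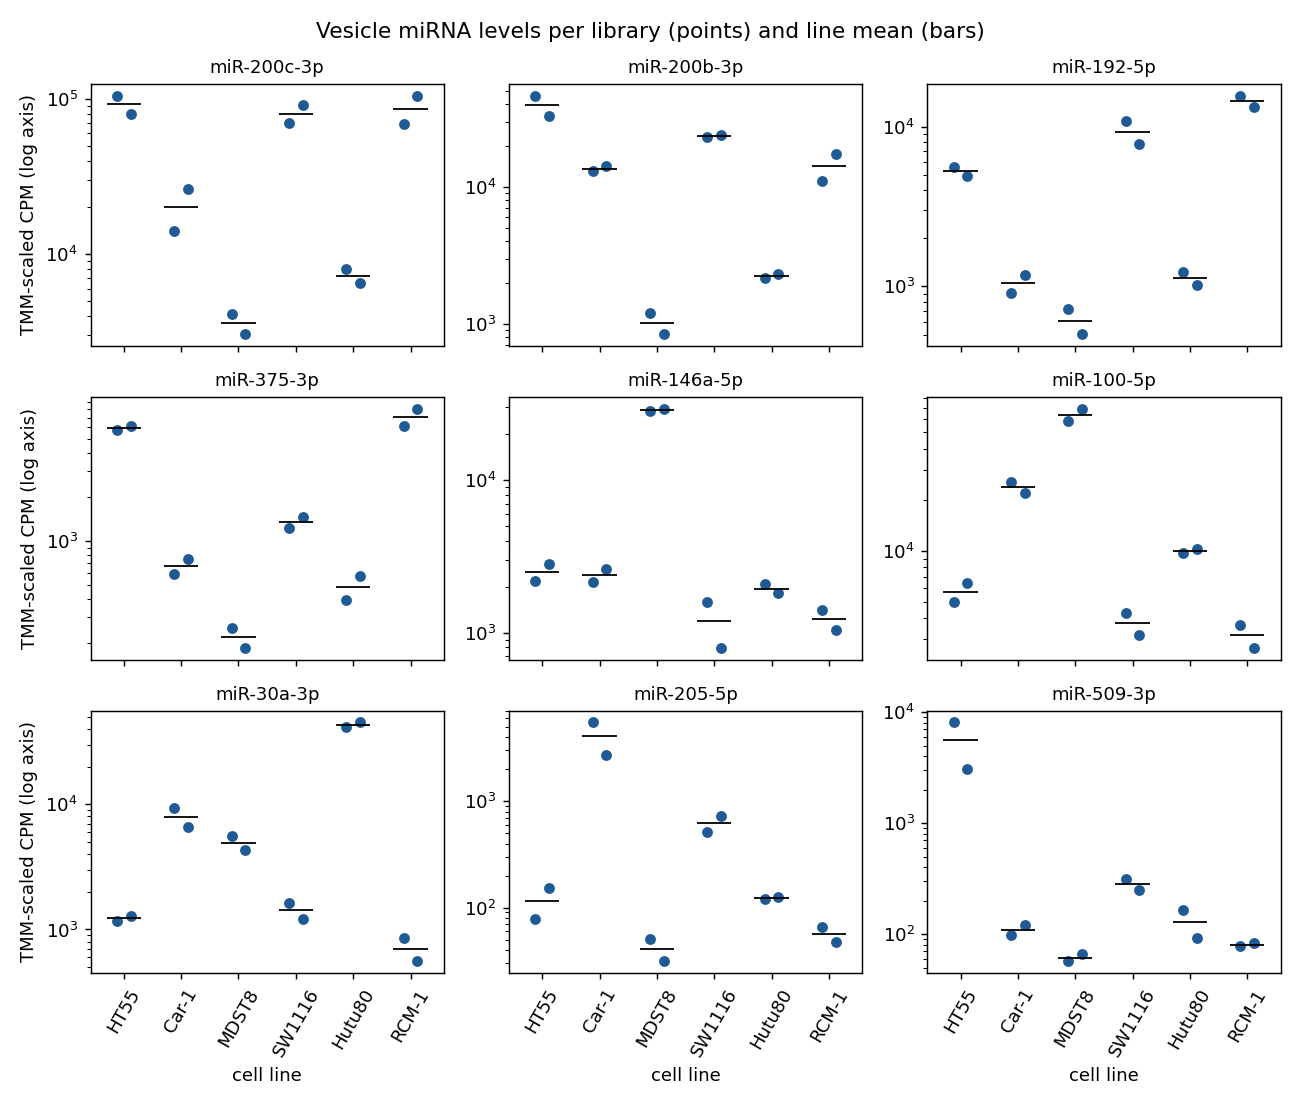
Scaled CPM of 9 miRNAs (logarithmic vertical axes) in each of the 12 libraries, grouped by line on the horizontal axis, with a bar at the mean of each line. miR-200c-3p, miR-200b-3p, miR-192-5p and miR-375-3p sit lowest in MDST8, where miR-146a-5p and miR-100-5p sit highest. miR-30a-3p is highest in Hutu80, miR-205-5p in Car-1 and miR-509-3p in HT55.

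Groups of related miRNAs were then compared, each line against the mean of the other 5. The miR-200 family, which represses the transcription factors ZEB1 and ZEB2 and helps to keep epithelial cells epithelial, differed among the lines. All 7 tested members were higher in SW1116 and in RCM-1 and 6 of 7 in HT55, while all 7 were lower in MDST8 and in Hutu80. miR-200c-3p (chromosome 12, 6963699 to 6963766, in an intron of MIR200CHG) was at 92305 ± 17950 CPM in HT55, 86297 ± 25165 in RCM-1 and 80348 ± 14865 in SW1116, against 20149 ± 8570 in Car-1, 7295 ± 1040 in Hutu80 and 3604 ± 775 in MDST8. miR-200b-3p (chromosome 1, 1167104 to 1167198, intergenic) was 2.64 ± 0.19 (SE) higher in HT55 (adjusted p = 4.83e-11) and fell by 3.70 ± 0.30 in MDST8 (2.07e-10). In HT55 the member not called was miR-141-3p, named here after its values were seen. The set test (camera with a preset correlation of 0.01) gave adjusted p = 8e-06 in HT55, 0.000174 in SW1116, 0.000178 in Hutu80, 0.000449 in MDST8 and 0.00169 in RCM-1. With an estimated correlation the adjusted p was 0.0829 in HT55, SW1116, Hutu80 and MDST8 and 0.108 in RCM-1. The estimate itself was 0.00907 in HT55 and 0.00245 in MDST8, below the preset 0.01, and 0.0131 to 0.0319 in Hutu80, RCM-1 and SW1116. A stronger correlation therefore cannot account for the loss in HT55 and MDST8, and both forms of the test differ in more than this value. In Car-1, 3 members were higher (miR-200a-3p, miR-200a-5p and miR-200b-3p) and the list did not pass (adjusted p = 0.316). Leaving out a library ended the call of miR-200b-3p in Car-1 (adjusted p = 0.124 without Car-1 replicate 2) and in RCM-1 (0.287 without RCM-1 replicate 2), of miR-200a-3p in Car-1 (0.0829 without Car-1 replicate 1), of miR-429 in RCM-1 (0.115 without RCM-1 replicate 1) and of miR-200b-5p and miR-200a-5p in SW1116 (0.416 and 0.138 without SW1116 replicate 2). The call of miR-200a-5p also ended in MDST8 without Hutu80 replicate 2 (1.0), and in RCM-1 without HT55 replicate 1 (0.0515) or 2 (0.0975), Car-1 replicate 1 (0.0531), SW1116 replicate 1 (0.0748), Hutu80 replicate 1 (0.0994) or RCM-1 replicate 2 (0.705), while the 5 set tests passed in all 12 such fits. In the other settings, the call of miR-200a-5p in RCM-1 ended in 8 of 9 (adjusted p = 0.0558 with RLE size factors to 0.267 in limma-trend) and that of miR-429 in limma-trend (0.0656). In SW1116, miR-200a-3p lost its call in limma-trend (0.0574), miR-200a-5p with library totals (0.0704) and in limma-trend (0.185), and miR-200b-5p with library totals (0.587), in DESeq2 (0.0529) and in limma-trend (0.563). All 7 members passed across lines, and 7 also did when adjusted over the list alone.

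The list of intestinal epithelial miRNAs was higher in RCM-1 and HT55 and lower in Car-1, calls that were lost with an estimated correlation (adjusted p = 0.108, 0.14 and 0.141 with an estimated correlation). miR-192-5p, an abundant miRNA of the gut epithelium that p53 induces (chromosome 11, 64891137 to 64891246, in an exon of MIR194-2HG), was at 14443 ± 1667 CPM in RCM-1, 9271 ± 2127 in SW1116 and 5261 ± 470 in HT55, against 1125 ± 142 in Hutu80, 1047 ± 188 in Car-1 and 612 ± 154 in MDST8. miR-194-5p, which hairpins on chromosomes 1 (beside miR-215) and 11 (beside miR-192) can both give, was 2.61 ± 0.19 higher in RCM-1 (adjusted p = 5.56e-11) and fell by 2.42 ± 0.27 in MDST8 (5.63e-08). Of 8 tested members, 6 were higher in RCM-1, with 2 lower when adjusted over the list alone (set test adjusted p = 0.00169). The higher ones were miR-192-5p, both arms of miR-194, miR-215-5p (a member of the same seed family), miR-375-3p and miR-196b-5p. Of these, miR-196b-5p lost its call in RCM-1 without RCM-1 replicate 1 (adjusted p = 0.0568). In HT55, 5 were higher and miR-31-5p was lower (0.00426), the latter call ending without HT55 replicate 1 (0.103). Car-1 had 4 lower members, miR-192-5p, both arms of miR-194 and miR-375-3p (0.00444). There the call of miR-375-3p ended without Car-1 replicate 1 (0.0612), and that of miR-194-3p without replicate 1 (0.0704) or 2 (0.14). Both also lost it with library totals (0.163 and 0.255) and in limma-trend (0.163 and 0.222), and miR-194-3p with no filter (0.14) and in limma-voom (0.0659). In MDST8 the list did not pass (0.136), with the 6 members named above as higher in RCM-1 lower here and miR-31-5p, a miRNA often raised in colorectal tumours, higher. The call of miR-215-5p in MDST8 (0.028) ended without Car-1 replicate 2 (0.118), MDST8 replicate 1 (0.266), Hutu80 replicate 1 (0.0665) or 2 (0.0781), with no filter (0.113) and in DESeq2 (0.0643). miR-31-5p was at 1642 ± 79.4 CPM in MDST8 (2.73 ± 0.25 higher, adjusted p = 1.38e-09) and 149 ± 39.0 in HT55. The list did not pass in Hutu80 (0.0631) or SW1116 (0.164), where its median changed sign with library totals. All 8 members passed across lines, and 8 also did when adjusted over the list alone.

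Among 14 tested miRNAs linked to epithelial-mesenchymal transition and inflammation, 13 were higher in MDST8. They included miR-146a-5p (4.04 ± 0.19 higher, adjusted p = 2.06e-14), miR-221-3p (28498 ± 872 CPM, 1.34 ± 0.18 higher, 9.9e-07), miR-222-3p (47984 ± 9245 CPM, 1.28 ± 0.20 higher, 8.51e-06) and miR-21-5p (181954 ± 49136 CPM, 1.25 ± 0.22 higher, 4.95e-05). The remaining member, miR-155-5p, a miRNA of activated immune cells, fell by 0.69 ± 0.27 in MDST8 (adjusted p = 0.0405), a call that ended in 7 of the 12 fits with a library left out (adjusted p = 0.0633 without HT55 replicate 2, 0.104 without Car-1 replicate 2, 0.447 without MDST8 replicate 2, 0.116 without SW1116 replicate 1, 0.136 and 0.0862 without Hutu80 replicate 1 or 2, and 0.102 without RCM-1 replicate 1), with RLE size factors (0.0872), with no filter (0.0784), in DESeq2 (0.0844) and without the 10 most abundant miRNAs (0.11). The call of miR-23a-3p in MDST8 ended without MDST8 replicate 2 (0.114). The list test gave adjusted p = 3.12e-05 in MDST8, and adjusted p = 0.0829 with an estimated correlation. In RCM-1, 5 members were lower and 2 higher (adjusted p = 0.0352, and adjusted p = 0.279 with an estimated correlation). The lower ones there were both arms of miR-221, miR-222-3p, miR-146a-5p and miR-24-3p, and the higher ones miR-29a-3p and miR-29b-3p, which target collagen messenger RNAs. Of these names, miR-221-5p, miR-24-3p and miR-29b-3p were chosen after their values were seen. In RCM-1, miR-222-3p lost its call without RCM-1 replicate 1 (0.129) or 2 (0.121), and miR-29a-3p likewise (0.0992 and 0.177), the latter also with library totals (0.14), with no filter (0.0661) and in limma-trend (0.157). The call of miR-221-3p there ended without HT55 replicate 1 (0.0615), MDST8 replicate 1 (0.0846) or 2 (0.094), SW1116 replicate 1 (0.0517) or 2 (0.0589), Hutu80 replicate 1 (0.0994) or 2 (0.121) or RCM-1 replicate 1 (0.331) or 2 (0.152), with no filter (0.059) and with the stricter filter (0.0686). The RCM-1 list call ended in limma-trend on the deposited log2 values (0.0513) and without the 10 most abundant miRNAs (0.0548). The list did not pass in Hutu80 (0.0505, or 0.0499 with RLE size factors), although 8 of 14 members were lower there and 1 higher. The miR-200 family was lower in Hutu80 too, so the 2 lists did not mirror each other in that line. Nor did the list pass in HT55 (0.0639, 5 lower and 1 higher), SW1116 (0.165, 2 lower and 4 higher) or Car-1 (0.24, 3 lower and 1 higher). In SW1116 and Car-1 its median changed sign with library totals as the only scaling. Across lines 13 of the 14 passed, all but miR-22-3p (chosen after its values were seen), and 13 also did when adjusted over the list alone.

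The list of miR-99/100, let-7c and miR-125b clusters took its largest share of counts in MDST8. There 5 of 6 tested members were higher (set test adjusted p = 0.00444, and adjusted p = 0.279 with an estimated correlation). In Hutu80, 3 members were higher, among them let-7c-5p, whose call ended without Hutu80 replicate 2. Car-1 had 3 higher and 1 lower. The neighbours miR-99a-5p and let-7c-5p had their highest median difference in Hutu80 (1.88, against 1.00 in MDST8). miR-100-5p (chromosome 11, 122152229 to 122152308, in an intron of MIR100HG) was at 63438 ± 7495 CPM in MDST8 and 23669 ± 2468 in Car-1, against 9998 ± 447 in Hutu80, 5738 ± 1078 in HT55, 3746 ± 767 in SW1116 and 3179 ± 699 in RCM-1. miR-125b-5p followed at 6620 ± 1814 CPM in MDST8 and 3698 ± 5.07 in Car-1. In HT55, 4 of the 6 were lower, or 5 adjusted over the list alone (set test 0.0146, and adjusted p = 0.304 with an estimated correlation), and this list call ended in limma-trend on the deposited log2 values (0.0554). Within it, miR-100-5p, miR-125b-5p, miR-99a-5p and miR-125b-2-3p lost their calls without HT55 replicate 1, and miR-125b-5p also without HT55 replicate 2. Such a fit leaves HT55 with a single library. A lost call therefore does not show that the left-out library drove the difference. In MDST8 the call of miR-125b-2-3p ended without MDST8 replicate 2 (0.124) and in limma-trend (0.0896), and its HT55 call also in limma-voom (0.0586). The list did not pass in SW1116 (0.0505, or 0.0499 with RLE size factors and 0.0479 with library totals), RCM-1 (0.0699), Hutu80 (0.226) or Car-1 (0.304). Yet 5 of 6 members were lower in SW1116 (median difference -1.55) and 3 in RCM-1 (-1.53), against a median of -1.03 in HT55. miR-99a-5p and miR-100-5p have near-identical sequences, so counts could be split between them. All 6 members passed across lines, and 6 also did when adjusted over the list alone.

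The let-7 family, which represses RAS and other growth genes, had 4 of 8 tested members higher in SW1116: let-7a-5p, let-7b-5p, let-7d-5p and let-7e-5p (set test adjusted p = 0.0163, and adjusted p = 0.452 with an estimated correlation; let-7e-5p was chosen after its values were seen). let-7b-5p reached 131407 ± 23865 CPM there, against 17142 ± 366 in MDST8 and 18303 ± 2135 in Hutu80. This list call ended with library totals as the only scaling (0.0783, where the median fell to -0.07), in limma-trend (0.0974) and without the 10 most abundant miRNAs (0.116). The call of let-7d-5p (0.65 ± 0.24 higher) ended without SW1116 replicate 2 (0.431), in DESeq2 (0.0588), in limma-trend (0.975) and with library totals (0.96), where its difference was -0.028. That of let-7a-5p ended with library totals (0.11) and in limma-trend (0.105). let-7i-5p went another way, at 15925 ± 759 CPM in MDST8 (2.02 ± 0.18 higher, adjusted p = 1.2e-09) and 2871 ± 506 in RCM-1. The let-7 list did not pass in Hutu80 (0.164), Car-1 (0.178), HT55 (0.583), RCM-1 (0.711) or MDST8 (0.733), and under library totals its median changed sign in Car-1, Hutu80 and RCM-1. In MDST8 the median (-0.01) and the mean (0.13) differed in sign, as they did in RCM-1 (0.01 and -0.18). Members of this family differ by 1 or a few bases, so counting could have split reads between them. Across lines 5 of the 8 passed, and 5 also did when adjusted over the list alone; the others were let-7f-5p (0.692), let-7g-5p (0.173) and miR-98-5p (0.122, chosen after its values were seen).

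miRNAs of the Xq27 cluster, which are expressed mostly in testis, were higher in HT55, with 3 of 3 tested members (set test adjusted p = 6.22e-05, and adjusted p = 0.161 with an estimated correlation). miR-509-3p, made by 3 hairpin copies (X chromosome, between 147258760 and 147260625, intergenic), was at 5589 ± 3518 CPM in HT55 and 61.6 ± 6.23 in MDST8. The list did not pass in MDST8 or RCM-1 (0.261 each), Car-1 (0.413), Hutu80 (0.517) or SW1116 (0.869), and its median changed sign with library totals in SW1116 and Car-1. The miR-34 family, whose members p53 induces, had too few tested members for a set test. Of its 2 members, miR-34a-5p was at 2712 ± 762 CPM in MDST8, 3.30 ± 0.27 higher than the mean of the other lines (adjusted p = 3.56e-10), and at 178 ± 11.5 in RCM-1. miR-34c-5p was at 42.8 ± 33.8 CPM in MDST8 and 30.3 ± 14.6 in Car-1, and its call in MDST8 ended without MDST8 replicate 1 (0.223) and that in Car-1 without Car-1 replicate 1 (0.322) or 2 (0.0859) and in DESeq2 (0.138). Both passed across lines, and 2 did when adjusted over the list alone, as did all 3 of Xq27.

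miRNAs embedded in the HOX gene clusters, which encode patterning factors, differed by member. All 6 tested passed across lines, and 6 did when adjusted over the list alone, while the list itself did not pass in any line (adjusted p = 0.0505 in Car-1, 0.0597 in Hutu80, 0.0635 in RCM-1, 0.136 in SW1116, 0.231 in HT55 and 0.675 in MDST8). Its median changed sign in SW1116 with library totals, under which the list passed in Car-1 (0.0427). miR-10b-5p was at 15977 ± 2379 CPM in MDST8 (2.01 ± 0.18 higher, adjusted p = 1.2e-09) and 2170 ± 241 in Car-1, whereas miR-10a-5p was at 405931 ± 8544 CPM in SW1116 (1.76 ± 0.18 higher, 3.29e-08) and 63961 ± 10480 in Car-1. miR-182-5p and miR-183-5p, sensory-organ miRNAs also raised in epithelial tumours, were higher in SW1116 and lower in Car-1 and RCM-1, and miR-182-5p was also higher in MDST8 (47458 ± 5158 CPM, 0.84 ± 0.21 higher, adjusted p = 0.0017). miR-182-5p was at 47212 ± 5618 CPM in SW1116 (0.83 ± 0.21 higher, 0.00313, but 0.0808 without SW1116 replicate 2, 0.508 with library totals and 0.447 in limma-trend) and 14999 ± 2213 in Car-1 (0.000558). In RCM-1 it fell by 0.96 ± 0.24 (0.00259, but 0.0729 without RCM-1 replicate 2). For miR-183-5p the SW1116 call ended without SW1116 replicate 2 (0.0595), with library totals (0.413) and in limma-trend (0.36), the Car-1 call with library totals (0.0916) and in limma-trend (0.0676), and the RCM-1 call without RCM-1 replicate 1 (0.0825) or 2 (0.128). Their cluster did not pass as a list (0.0505 in Car-1, or 0.0417 with library totals, 0.128 in SW1116, 0.258 in RCM-1, 0.333 in MDST8, 0.81 in HT55 and 0.852 in Hutu80), its median changed sign in HT55 with library totals, and 2 of its 3 members passed across lines, 2 also when adjusted over the list alone.

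Of 18 tested members of the miR-17-92 cluster and its paralogs, which promote cell proliferation, 8 passed across lines, and 8 did when adjusted over the list alone. With library totals as the only scaling 14 passed, and in limma-trend 14. miR-92a-3p was at 128855 ± 1610 CPM in RCM-1 and 110434 ± 12050 in HT55, against 16638 ± 142 in MDST8, where it fell by 2.12 ± 0.25 (adjusted p = 1.73e-07). Hutu80 had 6 higher members and 1 lower one, among them miR-363-3p at 6208 ± 1151 CPM (5.26 ± 0.55 higher, 4.56e-05) and miR-92a-1-5p at 7129 ± 3970 (3.98 ± 0.24 higher, 1.3e-12), with the lower one being miR-25-3p (0.0162, but 0.238 with library totals and 0.193 in limma-trend). The Car-1 libraries stood apart from each other here: miR-363-3p had an unscaled level of 3826 CPM in replicate 1 and 552 CPM in replicate 2, and its call in Car-1 (0.00454) ended without replicate 1 (0.111). The list did not pass in any line (0.068 in Hutu80, or 0.035 with library totals, 0.0739 in SW1116, or 0.0266, 0.164 in MDST8, 0.261 in RCM-1, 0.835 in HT55 and 0.971 in Car-1). Its median and mean differed in sign in HT55 (0.12 and -0.14) and RCM-1 (0.41 and -0.02). Close paralogs such as miR-106a and miR-17, or miR-20b and miR-20a, may share counts.

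Markers of other cell types were measured as well. The list of blood cell and serum miRNAs took 0.684% ± 0.072 of counts in Car-1, 0.592% ± 0.068 in HT55, 0.559% ± 0.094 in Hutu80, 0.289% ± 0.057 in RCM-1, 0.229% ± 0.021 in MDST8 and 0.168% ± 0.059 in SW1116. The medium contained fetal bovine serum, per the labels. The most abundant member, miR-486-5p of red blood cells, was at 4428 ± 456 CPM in HT55 (1.20 ± 0.22 higher, adjusted p = 0.000112) and 1322 ± 231 in MDST8 (0.00553, but 0.136 without MDST8 replicate 2). The lymphocyte miRNA miR-150-5p was at 651 ± 116 CPM in RCM-1 and 56.9 ± 22.8 in MDST8. These were the 2 of 11 tested members that passed across lines, and 2 did when adjusted over the list alone. With library totals as the only scaling 7 passed, and in limma-trend 6. Fibroblast and smooth muscle miRNAs took 0.0279% to 0.0981% of counts, with the lines in the same order as for the serum list. Of 4 tested members 2 passed, miR-1-3p (42.7 ± 11.5 CPM in MDST8) and miR-143-3p (275 ± 2.59 in Hutu80, 113 ± 13.7 in SW1116), and 2 did when adjusted over the list alone. Of 6 tested miRNAs of the imprinted 14q32 cluster, 0 passed across lines in edgeR with trimmed-mean factors or when adjusted over the list alone (2 at an unadjusted p below 0.05). With library totals as the only scaling 4 passed, with 0 in DESeq2, 1 in limma-voom and 3 in limma-trend. No line passed the set test for the serum list (smallest adjusted p 0.0889, HT55), the fibroblast list (0.231, HT55) or 14q32 (0.341, RCM-1), and in Hutu80 the fibroblast list had a median of 0.55 and a mean of 0.14 beside a test direction of down. No member of the placental C19MC cluster or of the stem cell miR-371-373 cluster was tested, the highest counts over all 12 libraries being 14 and 9. Over all lists, 14 of 72 tests passed with the preset correlation (27 at an unadjusted p below 0.05) and 0 of 72 with an estimated one (10 at an unadjusted p below 0.05). The estimate was far above the preset 0.01 for Xq27 in HT55 (0.758) and let-7 in SW1116 (0.412). It was also above for the miR-99/100 list in HT55 (0.226) and MDST8 (0.220). The preset p-values of these passes may therefore be too small. For the other passes the estimate was at most 0.0494. More list tests passed in every fit that left out a library, but these fits also filtered low counts less strictly. The effect of the left-out library therefore cannot be told apart from that of the looser filter.

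Each line was then set against the mean of the other 5 to see which miRNAs marked its vesicles. Of the 5 higher miRNAs named for HT55, 4 were X-linked. miR-509-3p was 5.60 ± 0.25 higher (5589 ± 3518 CPM against a mean of 133 in the other 10 libraries, adjusted p = 5.27e-15), and its neighbour miR-508-3p was higher too (436 ± 255 against 10.5 CPM, 5.3e-09). miR-513a-5p had 37 counts in HT55 and 3 in all other libraries together, a ratio of 99.8 in unscaled CPM with a 95% counting interval of 31.6 to 506. miR-3937 (X chromosome, 39661216 to 39661321, intergenic) was at 358 ± 218 against 4.98 CPM, and miR-1247-5p (chromosome 14, 101560287 to 101560422, in an exon of DIO3OS) was at 2590 ± 526 against 293 CPM (4.95e-12). In the other direction, miR-21-5p was at 43548 ± 4007 CPM against 110326, a fall of 1.22 ± 0.27 (0.00108). In all, 44 miRNAs were higher and 33 lower (111 at an unadjusted p below 0.05), of which 18 higher and 4 lower also lay outside the range of the other libraries at a mean of at least 100 CPM. The count of lower miRNAs was 9 without HT55 replicate 1 and 16 without HT55 replicate 2, and that of higher miRNAs 67 without Car-1 replicate 2. The hypoxia-induced miR-210-3p (adjusted p = 0.0303, 0.144 without HT55 replicate 1, 0.23 without HT55 replicate 2, 0.0749 without Car-1 replicate 1 and 0.142 in limma-voom), miR-193b-3p (0.0175, 0.309 and 0.0532 without HT55 replicate 1 or 2, 0.0658 with no filter and 0.0722 in limma-voom) and miR-671-5p (0.0145, 0.0603 and 0.302 without HT55 replicate 1 or 2, and 0.0672 in limma-voom) were lower in the full fit.

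Car-1 vesicles stood out by miR-205-5p (chromosome 1, 209432133 to 209432242, in an exon of MIR205HG), at 4109 ± 1971 CPM against 191 in the other lines, a difference of 5.14 ± 0.25 (adjusted p = 4.39e-14). miR-934, from an intron of VGLL1 (X chromosome, 136550878 to 136550960), was at 196 ± 72.8 against 6.53 CPM (6.74e-06). miR-345-3p was at 467 ± 109 against a mean of 56.8 CPM (6.02e-10), with up to 319 CPM in a Hutu80 library and none counted in HT55. miR-5100 was 4.11 ± 0.42 higher, and miR-10527-5p was at 214 ± 107 against 17.6 CPM. Of the 5 lower miRNAs named for Car-1, 3 lie in HOX clusters, a list that did not pass there (adjusted p = 0.0505, and adjusted p = 0.279 with an estimated correlation): miR-10b-5p fell by 1.45 ± 0.23 (2170 ± 241 against 7089 CPM, 2.04e-05), miR-10a-5p by 1.44 ± 0.23 (1.95e-05) and miR-196a-5p by 1.44 ± 0.33 (0.00129). Another member of that list, miR-615-3p, was 2.01 ± 0.56 higher in Car-1 (0.0072, but 0.0842 without Car-1 replicate 1). miR-378a-3p, encoded in a gene of mitochondrial metabolism, fell by 1.26 ± 0.25 (0.000321). miR-652-3p fell by 1.20 ± 0.45 (0.0429), and this call ended without HT55 replicate 2 (0.0577), Car-1 replicate 1 (0.11) or 2 (0.122), SW1116 replicate 1 (0.0619) or RCM-1 replicate 2 (0.0745), and in 5 of the 9 other settings (0.0582 in DESeq2, 0.113 in limma-voom, 0.141 with no filter, 0.315 with library totals and 0.396 in limma-trend). The counts were 67 higher and 43 lower (140 at an unadjusted p below 0.05), 13 and 10 of them outside the range of the other libraries, and 21 were lower without Car-1 replicate 1. With library totals as the only scaling, 117 were higher and 12 lower.

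MDST8 had the largest count of miRNAs that differed from the other lines, although counts were not tested against each other. miR-708-5p, from an intron of TENM4 (chromosome 11, 79402022 to 79402109), was at 621 ± 183 CPM against 21.8 (adjusted p = 1.26e-10). miR-455-3p, from an intron of the cartilage collagen gene COL27A1 (chromosome 9, 114209434 to 114209529), was 4.13 ± 0.32 higher (950 ± 419 against 63.6 CPM), and miR-1269b 4.12 ± 0.31 higher (846 ± 177 against 50.4 CPM). miR-296-3p (107 ± 17.1 against 11.5 CPM) and miR-31-3p (205 ± 32.8 against 16.9 CPM) completed the 5 largest rises. On the lower side, miR-200b-3p, miR-200c-3p and miR-200a-3p had differences of -3.70 ± 0.30, -3.45 ± 0.32 and -3.21 ± 0.36. Also lower were miR-92a-1-5p, with -3.49 ± 0.40 (94.9 ± 54.3 against 2219 CPM, 7.28e-08) and miR-203a-3p, with -3.19 ± 0.30 (221 ± 68.7 against 3327 CPM, 2.53e-09). The totals were 70 higher and 71 lower (158 at an unadjusted p below 0.05), with 43 and 27 outside the range of the other libraries. No library moved either count by more than 1.5 times when left out, and the 10 miRNAs named for MDST8 passed in every such fit and in every other setting.

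SW1116 vesicles were rich in let-7b-5p (chromosome 22, 46113686 to 46113768, in an exon of MIRLET7BHG), at 131407 ± 23865 CPM against 38271, a difference of 2.05 ± 0.21 (adjusted p = 3.29e-08). miR-577, from an intron of UGT8 (chromosome 4, 114656759 to 114656854), was at 119 ± 26.5 against 10.4 CPM (6.1e-05). The neuronal miRNA miR-9-3p was 2.98 ± 0.36 higher (411 ± 84.9 against 61.5 CPM, 3.67e-07), miR-338-5p 2.91 ± 0.42 higher (6.72e-06) and miR-574-5p 2.20 ± 0.22 higher (3180 ± 47.0 against 836 CPM, 2.56e-08). miR-140-3p, a cartilage miRNA, fell by 1.78 ± 0.30 (214 ± 50.5 against 820 CPM, 5.24e-05). miR-342-3p fell by 1.67 ± 0.41 (0.00313, but 0.142 without SW1116 replicate 2) and miR-500a-3p by 1.33 ± 0.38 (0.00983, but 0.0501 and 0.168 without SW1116 replicate 1 or 2, and 0.128 with no filter). Together 56 miRNAs were higher and 53 lower (132 at an unadjusted p below 0.05), 13 and 3 of them outside the range of the other libraries. Without SW1116 replicate 2, 32 were higher and 17 lower, and the count of lower miRNAs was also 28 without HT55 replicate 2, 30 without SW1116 replicate 1, 33 without Hutu80 replicate 2 and 34 without Car-1 replicate 2. With library totals as the only scaling, 28 were higher and 104 lower.

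Hutu80 vesicles carried miR-1262, from an intron of the WNT secretion gene WLS (chromosome 1, 68183518 to 68183610), at 1696 ± 619 CPM against 36.7, a difference of 5.51 ± 0.30 (adjusted p = 2.66e-13). miR-137-3p, a miRNA of the nervous system, and miR-2682-5p, from exons of MIR137HG (chromosome 1, 98045242 to 98046171), were at 395 ± 107 against 27.0 CPM (1.16e-08) and 177 ± 12.7 against 3.15 CPM (7.84e-07), with up to 140 CPM of miR-137-3p in an MDST8 library. miR-30d-3p was at 419 ± 57.7 against 20.8 CPM (1.12e-08), and miR-3180-3p, which several hairpins can give, at 109 ± 0.15 against 9.08 CPM. Among lower miRNAs, miR-200a-5p had 1 count in Hutu80 and 458 elsewhere, the others being 26.6 times higher in unscaled CPM (95% counting interval 4.75 to 1053). The same ratio was 14.6 for miR-2110 (1 and 251 counts, 2.59 to 578) and 5.77 for miR-135b-5p (3 and 298 counts, 1.95 to 28.1), a miRNA often raised in colorectal cancer. miR-29a-3p fell by 1.69 ± 0.27 (1159 ± 47.4 against 5556 CPM, 2.1e-05) and miR-574-3p by 1.67 ± 0.59 (0.0271, but 0.219 without Hutu80 replicate 1 and 0.0739 with library totals). The counts were 73 higher and 53 lower (147 at an unadjusted p below 0.05), 36 and 11 of them outside the range of the other libraries, and 43 were higher without Hutu80 replicate 2. With library totals as the only scaling, 94 were higher and 33 lower.

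Of the 5 higher miRNAs named for RCM-1, 3 were on the intestinal list. miR-375-3p was at 7073 ± 1341 CPM against 1730, a difference of 2.98 ± 0.19 (adjusted p = 1.08e-11), miR-192-5p 2.83 ± 0.18 higher (1.08e-11) and miR-215-5p 3.09 ± 0.44 higher (271 ± 22.5 against 38.5 CPM, 5.25e-06). miR-224-5p, within the GABRE gene (X chromosome, 151958578 to 151958658, exonic), was at 10433 ± 667 against 2568 CPM, 2.80 ± 0.19 higher (1.85e-11), and miR-150-5p 2.81 ± 0.32 higher. Lower miRNAs included both arms of miR-99b (chromosome 19, 51692612 to 51692681, in an intron of SPACA6), which fell by 3.87 ± 0.54 (28.8 ± 24.0 against 549 CPM, 3.97e-06) and 2.64 ± 0.31 (3.9e-07), and both arms of miR-30a (chromosome 6, 71403551 to 71403621, in an intron of a long non-coding RNA), with differences of -3.01 ± 0.33 for the 5p arm (2335 ± 589 against 34203 CPM, 1.33e-07) and -2.82 ± 0.28 for the 3p arm. miR-1275 fell by 3.02 ± 0.55 (22.8 ± 13.8 against 396 CPM, 0.00011). Here 67 miRNAs were higher and 47 lower (142 at an unadjusted p below 0.05), 15 and 13 of them outside the range of the other libraries. Without RCM-1 replicate 1, 44 were higher and 31 lower, and 29 were lower without RCM-1 replicate 2. With library totals as the only scaling, 53 were higher and 59 lower.

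**Figure D3:**
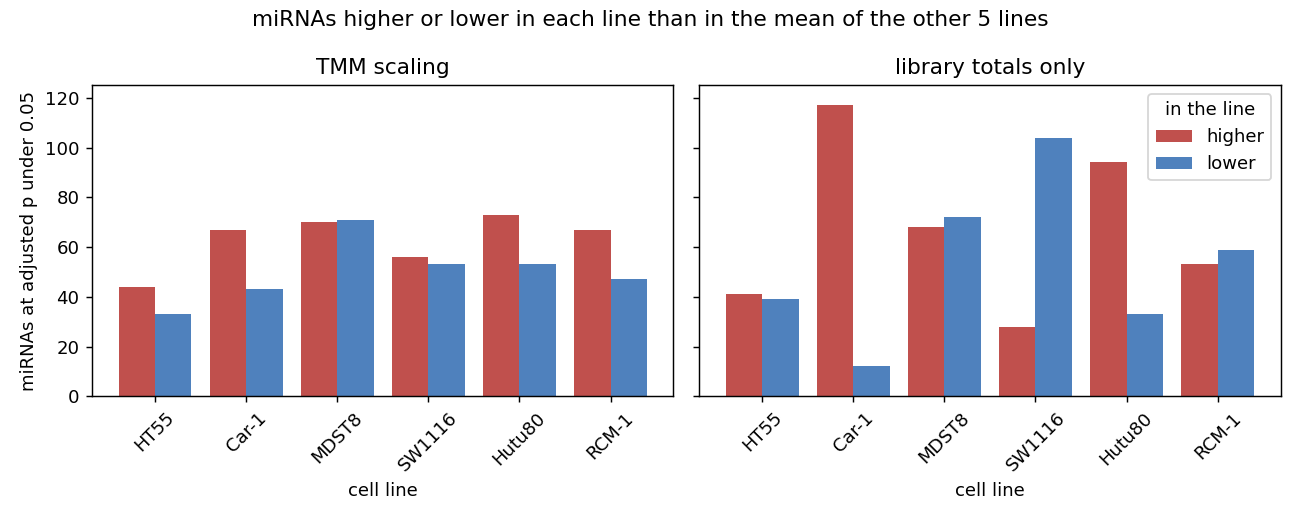
Number of tested miRNAs (vertical axis, from 0) higher or lower in each line than in the mean of the other 5 at an adjusted p below 0.05, with trimmed-mean scaling beside library totals only. With totals the split of higher to lower goes from 67 and 43 to 117 and 12 in Car-1 and from 56 and 53 to 28 and 104 in SW1116, and stays near equal in MDST8.

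The scaling mattered because the median difference over all tested miRNAs moved with it. With library totals the median was 0.64 in Car-1, 0.44 in Hutu80, -0.17 in HT55, -0.29 in RCM-1, -0.32 in MDST8 and -0.88 in SW1116, against 0.02, 0.09, -0.08, -0.12, -0.32 and -0.22 with trimmed-mean factors. Of the 57 miRNAs named by line, 51 passed in the same direction in every alternative other than leaving out a library and 50 in every fit with a library left out.

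Lines were also compared in pairs. The fewest miRNAs differed between HT55 and RCM-1 and between SW1116 and RCM-1 (43 each), followed by Car-1 and Hutu80 (58) and HT55 and SW1116 (65), and the most between SW1116 and Hutu80 (140). The median over the 15 pairs was 125. Since the series names a comparison of 3 lines with 3, all 10 ways to split the 6 lines evenly were tested on counts summed per line, without saying which of them is the split by subtype. These gave 0 to 39 miRNAs at an adjusted p below 0.05 in edgeR, with a median of 0, and 1 of the 10 splits had any. At an unadjusted p below 0.05 the splits gave 6 to 78 miRNAs, with a median of 13.5. With no filter on low counts the splits gave 2 to 74, with a median of 5 and a call in 10 of the 10. DESeq2 gave a median of 7.5 and a highest count of 61, with a call in 8 of the 10 splits, and limma with the line as a random block a median of 0 and a highest count of 31.

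At equal depth the lines differed in how many miRNAs were detected. Thinned to the smallest library total (71831 counts), Car-1 libraries showed 541 ± 15.6 miRNAs with at least 1 count, Hutu80 460 ± 14.1, HT55 419 ± 34.3, MDST8 393 ± 14.8, RCM-1 389 ± 25.6 and SW1116 361 ± 15.6. The distance between Car-1 and the next line was larger than the SD of either. Most of these miRNAs had few counts, and detection depends on the minimum set.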

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

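The alternatives named here were chosen before the data were examined. Fits that left out a library also re-ran the filter with a smallest group of 1 library, so the miRNAs tested changed with them. Of 317 differences between a named miRNA's line and the other lines that passed the threshold, 309 kept their direction and their side of the threshold with RLE size factors, 280 with library totals, 273 with no filter, 297 with the stricter filter, 288 in limma-voom and 272 in limma-trend. DESeq2 kept 291 of the 316 it tested, and 267 of 277 were kept without the 10 most abundant miRNAs. Leaving out 1 library kept 281 to 295, the lone library of that line being assumed to vary like the other lines. In all, 193 were kept in every such fit and 229 in every other alternative.

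Some counts moved by more than 1.5 times. With library totals, 117 miRNAs were higher and 12 lower in Car-1, 28 higher and 104 lower in SW1116, and 33 lower in Hutu80. With no filter, 23 were lower in Car-1 and 23 in SW1116, 37 list tests passed, and the median over the 10 splits was 5. The filter of 10 CPM in 2 libraries, which kept low-count miRNAs that the main filter dropped, gave 28 passing list tests. In limma-trend on the deposited log2 values, 50 were lower in HT55, 15 lower in Car-1, 24 higher and 105 lower in SW1116, and 43 higher in RCM-1. With an estimated correlation, 0 list tests passed in camera (10 at an unadjusted p below 0.05). DESeq2 gave a median of 7.5 over the splits. Limma-trend and library totals share the absence of a scaling factor, and the cause of the other moves was not tested.

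The direction of 3 differences reversed among named miRNAs. let-7d-5p in SW1116 went from 0.65 to -0.028 with library totals and -0.013 in limma-trend, and miR-25-3p in Car-1 from -0.61 to 0.023 and 0.020. miR-5100 in HT55 went from 2.02 to -0.69 without HT55 replicate 2 (adjusted p = 0.653), and to 2.88 without HT55 replicate 1.

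Over the fits that left out 1 library, 219 to 242 miRNAs differed across lines, 17 to 25 list tests passed and the median over pairs was 98 to 119. The counts of higher and lower miRNAs were 42 to 67 and 9 to 41 in HT55, 46 to 77 and 21 to 46 in Car-1, 60 to 98 and 53 to 69 in MDST8, 32 to 67 and 17 to 47 in SW1116, 43 to 78 and 42 to 69 in Hutu80, and 44 to 74 and 29 to 53 in RCM-1.

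With the replicate number as a block, 223 miRNAs differed across lines, 15 list tests passed, the median over pairs was 128, and 312 of the 317 differences were kept. The labels used here do not say whether same-numbered libraries were handled together. Deviations from the line means correlated between same-numbered libraries at -0.228 to 0.266 (median 0.0619), above 0.1 in 5 of 15 pairs of lines. These values do not decide whether same-numbered libraries shared a batch. The planned comparison of subtypes was not run, as no label gives each line's subtype.

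Detection depended on the minimum and on depth. With a minimum of 10 counts at equal depth, 155 miRNAs were detected in HT55, 197 in Car-1, 153 in MDST8, 135 in SW1116, 188 in Hutu80 and 149 in RCM-1. Without thinning the means were 522, 683, 531, 611, 479.5 and 544, at unequal depths.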

Other observations

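The tests chosen only after the result was seen are both tests of a common rate of misassigned reads, the co-movement of serum miRNAs, both tests on Car-1 replicate 1 and the matched detection of late-numbered miRNAs. The miRNA clusters described next were also chosen after the values were seen.

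Over 28 clusters of neighbouring hairpins and 6 lines, 56 of 168 combinations had at least 2 miRNAs that passed, all in the same direction in 52 and in both directions in 4, arms of 1 hairpin included, and this was not tested against chance. The 4 were the clusters of miR-221 with miR-222, miR-30b with miR-30d, and miR-25 with miR-93 and miR-106b in Hutu80, and that of miR-23a with miR-27a in SW1116. The clusters described next were picked from the 52. In the cluster of miR-363, miR-92a-2, miR-20b, miR-18b and miR-106a (X chromosome, 134169378 to 134170278), all 7 tested miRNAs were higher in Hutu80 and 6 in Car-1, where miR-363-3p lost its call without Car-1 replicate 1 (adjusted p = 0.111). Left-out fits are given here for miRNAs within the naming rule. At miR-30c-2 and miR-30a (chromosome 6, 71376960 to 71403621), 3 of 3 were higher in Hutu80 and in Car-1 and 3 of 3 lower in HT55, SW1116 and RCM-1, but in Car-1 miR-30a-5p lost its call without Car-1 replicate 1 (adjusted p = 0.518). At miR-99b, let-7e and miR-125a (chromosome 19, 51692612 to 51693339), all 4 were lower in RCM-1 and in HT55, where miR-99b-3p lost its call in limma-voom (adjusted p = 0.0589). Both miR-224-5p and miR-452-5p (X chromosome, 151958578 to 151959712) were higher in RCM-1 and SW1116 and lower in MDST8. miR-216b-5p and miR-217-5p, known from pancreas (chromosome 2, 55982967 to 56000795), were higher in Car-1 (104 ± 83.1 and 65.3 ± 57.0 CPM, SD, n = 2) and in Hutu80 (50.0 ± 24.3 and 58.8 ± 83.1 CPM) than in the mean of the other lines, with SDs near or above the means for miR-217-5p, which had a count in only 1 of the 2 Hutu80 libraries. Of the 8 miRNAs tested at miR-532 to miR-502 (X chromosome, 50003148 to 50014683), 5 were higher in Hutu80, and miR-500a-3p lost its call there without Hutu80 replicate 1 (adjusted p = 0.0523).

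For 9 miRNAs counted mainly in 1 line (at least 10 times the level and 100 counts), the other lines held 1.57% to 5.60% of that line's level in unscaled CPM, with a median of 3.01%, and 5 of the 9 had a count in all 10 other libraries. Reads assigned to a wrong library at 1 common rate, as the whole source, would leave no miRNA below that rate in any line. Yet 28 of 318 tested miRNAs lay below it in some line (lowest upper limit 0.0620 of the pooled level, miR-92a-2-5p in SW1116, where the rate needed was 0.134). This argues against an equal rate in every library. The lines concerned were mostly MDST8, SW1116 and RCM-1, which had the most counts, and never Car-1 or Hutu80. A set number of stray reads would be a smaller share of a deeper library, so misassignment that varies with depth stays open as the whole source. A common rate as part of the source also stays open, since the 10th percentile of the share of the pooled level was 0.472 of the 90th, above the 0.33 predicted for it. Serum vesicles in the medium also stay open: the slope of the log2 level on the log2 share of the serum list over the 6 lines was 0.349 (0.210 to 0.667 leaving out a line; Pearson r = 0.646, exact permutation p = 0.185, adjusted 0.185; Spearman rho = 0.543, exact p = 0.297, adjusted 0.297; r = 0.810 without SW1116 and MDST8), in a family of 2 relations. Serum list members moved together between replicates more than random lists of the same size matched on mean count (mean correlation 0.364 against a median of 0.0200, percentile 99.9), but the level followed the list in only 4 of 6 lines, and low expression in each line was not tested apart.

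Over the 6 lines the serum list's share correlated negatively with the mean total count (r = -0.892, two-sided exact permutation p = 0.0181, adjusted 0.0361). The rank correlation was rho = -0.829 (exact permutation p = 0.0583, adjusted 0.117), and r was -0.993 without SW1116 and Hutu80. This was the other relation of that family. The order of lines was not particular to the serum list. The fibroblast and smooth muscle list had the same order, from 0.0981% of counts in Car-1 to 0.0279% in SW1116. The 14q32 list also ran from 0.102% in Car-1 to 0.0272% in SW1116, with a different order between these ends. The serum list's share may therefore not measure serum alone.

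Of 7 members of the X-chromosome cluster, 4 were several times higher in Car-1 replicate 1 than in replicate 2 in unscaled CPM, by 7.26 times for miR-106a-5p, 6.96 for miR-20b-5p, 6.94 for miR-363-3p and 4.44 for miR-20b-3p, while the ratio was 2.39 for miR-18b-5p (6 and 2 counts), 1.22 for miR-363-5p and 1.04 for miR-92a-2-5p (259 and 199 counts, 95% interval 0.859 to 1.25), against a median of 1.04 over all tested miRNAs. Counting error is argued against for these 4 of 7 members, whose intervals lie above that median, while the other 3 intervals do not exclude it. RNA or reads of Hutu80, in which the cluster is highest, would bring other Hutu80 miRNAs along. The rise of 8 such miRNAs, as a share of the Hutu80 level, had a median 0.0952 times that of the 4 members (upper quartile 0.301 against a lower quartile of 0.546), and miR-1262 was at an unscaled 40.5 CPM in replicate 1 and 94.4 in replicate 2, which argues against it, although miR-99a-5p (0.481) lay within the cluster's range of 0.465 to 0.685. No biological explanation was tested, and reads shared with the near-identical miR-17, miR-20a and miR-18a may contribute but were not tested.

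More miRNAs were detected in Car-1 than in any other line at equal depth. A few abundant miRNAs taking most counts elsewhere stays open: without the 10 most abundant, at 30069 counts, Car-1 showed 525 ± 21.4 miRNAs and Hutu80 446 ± 8.62, a ratio of 1.18 that is above what it predicts but exceeds the bound set for excluding it by less than the SD of Car-1. SW1116 and RCM-1 then showed 411 ± 14.8 and 411 ± 28.7, against 361 ± 15.6 and 389 ± 25.6 with all miRNAs at 71831 counts. Fragments of other RNAs counted as miRNAs numbered 1200 or above stay open, because the Car-1 excess was 1.53 times as large among these as among lower numbers, as predicted for it. At matched counts in the other lines it was 0.986 times (167.8 detected against 170.2 expected), which goes the other way, so these 2 tests do not decide. By share of counts, miRNAs numbered 1200 or above took 2.83% in Car-1, below HT55 (5.29%) and Hutu80 (3.81%). That share was above those of MDST8 (1.67%), RCM-1 (0.953%) and SW1116 (0.717%). A broader release of miRNAs by Car-1 stays untested.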
